A study of Mus musculus with 33 samples.

How the data were processed

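Single-cell RNA sequencing libraries were made from the dura mater, the blood and the tibial marrow of young and aged C57BL/6 mice, per the labels. The dura mater is the outer of the membranes around the brain and lies against the skull. The chemistry was the 10x Chromium 5' gene expression kit run with immune receptor libraries, sequenced on a NovaSeq, per the labels' protocols. Each of the 33 libraries was deposited as an unfiltered matrix of whole-number counts, in which a value is the number of unique molecular identifiers (UMIs) of a gene in a droplet barcode. The authors deposited these UMI counts unnormalised, for 31053 genes and for every possible barcode, so empty droplets were still in them. The submitters' processing notes name Cell Ranger 3.1.0, Seurat without a version, and the build GRCm38 (mm10). The alignment settings, the filters on cells and the cell annotation used by the submitters are not given in the sources used here. The immune receptor libraries were not analysed here.

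Tissue, age and number were taken from the labels, which give 6 groups. The series text describes 2 sequencing batches, with 3 mice per age and tissue in the first, and 3 young and 4 aged mice for blood and dura in the second. Marrow libraries carry only the numbers 1 to 3, so the numbers 1 to 3 were taken as batch 1 and the numbers 4 to 7 as batch 2. This is an inference from the numbering, and it leaves 1 discrepancy, since 4 young dura labels, and 3 young blood labels, carry numbers above 3. Libraries of a group came from separate mice, per the series text. Whether equal numbers in different tissues mark the same mouse is not stated. Before any average, the libraries of each group were compared gene by gene by chi-square, and the closest pair, of young marrow, still differed beyond sampling noise (chi-square per degree of freedom of 1.50), so none was taken as a copy of another.

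The groups, the tests, the markers, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. A barcode was kept with at least 500 UMIs, at least 5 times the median UMI total of the barcodes ranked 20001 to 60000 in its library, at least 250 genes and at most 10 percent mitochondrial UMIs. In 6 blood libraries of batch 1 the second of these limits was the higher, at 1275, 1350 and 870 UMIs in young libraries 1, 2 and 3 and at 680, 4575 and 2075 UMIs in aged libraries 1, 2 and 3. Doublets were scored in each library against simulated doublets by nearest neighbours in principal components. The top cells were removed at 0.8 percent per 1000 cells kept, and clusters with over 40 percent of such cells were left out. Free RNA was estimated per library from barcodes with 10 to 100 UMIs, and the share of a gene's counts it could account for was scaled on lists of other cell types with at least 50 free UMIs. This scaling was changed after its first result had been seen.

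Cells were clustered per tissue on 2000 variable genes, 40 principal components, 15 neighbours and the Leiden method at resolution 2.0 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9). The 86204 B lineage cells were then clustered again together, on genes without immunoglobulin and T cell receptor segments, mitochondrial, ribosomal protein and sex-linked genes. From this step 673 genes of red cells and platelets were also left out, a choice made after seeing that they split the blood cells. It gave 48 clusters, and 1846 cells of clusters under 20 cells were moved to their nearest neighbours' cluster. A cluster was called "X-like" only by markers in the fixed lists, with at least 3 of them detected and with no more markers of another class than of its own among its top 10 genes. No cluster of the dura passed for endothelial cells, so that planned comparison was not run. Because the names were rebuilt here, shares can differ from those of the study. Mature B covers every B lineage cluster past the immature stage other than plasma cells. It includes the cluster like age-associated B cells (ABC), a type defined by Tbx21 and Itgax and known to accumulate with age, and the clusters like B1 cells, the innate-like B cells common in body cavities. Developing B covers the pro-B-like, cycling pre-B-like, pre-B-like and immature-like clusters.

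A share is a percent of the named leukocytes, or of the B lineage cells, of 1 library. Shares were compared by exact two-sided permutation tests of the difference of means over all regroupings of the libraries, with Benjamini-Hochberg adjustment over the classes of a family. Differences of an age effect between dura and blood were tested by 100000 permutations of the ages within each tissue, a test whose null is no age effect in either tissue. With 3 libraries against 3 the smallest exact p is 0.1, and chance alone separates a class completely in 10% of cases.

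For expression, raw counts were summed per library and cell class, over libraries with at least 20 cells of the class. Genes passing filterByExpr were scaled by TMM and tested with edgeR's quasi-likelihood test (robust glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3), with batch as a term where both batches entered. The term was tissue, age or their product for the comparisons between dura and blood. Adjusted p-values of genes are those of edgeR with Benjamini-Hochberg adjustment over the genes tested, called at 0.05, unless another tool is named. Levels are CPM, counts scaled to a common library total by TMM, given as mean ± SD over libraries, and log2 fold changes are given ± their standard error (SE). Gene lists with at least 6 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. Camera was run on log CPM with the design of the fit. The plan had spoken of ranking by the edgeR statistic, which was not done. "Rose" and "fell" count members past the threshold over all genes tested, and a second count is adjusted over the list alone. The list of ribosomal proteins, taken by symbol, also holds a few kinases named Rps6k.

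The text names, per comparison, the genes with the largest changes each way among those past the threshold, with a mean of at least 20 CPM in 1 of the groups and the same direction in each batch that entered. The number was 10 each way for B cells and 5 for other classes, without immunoglobulin and T cell receptor segments, mitochondrial, haemoglobin and sex-linked genes and unnamed gene models. It adds members of the lists of ABC, follicular B cell and isotype genes in mature B cells, and the 4 members with the smallest p of each list called by camera. Of these, 121 are printed, all with an identifier and coordinates in GENCODE annotation of GRCm38, and a few others are not reported here. Total UMIs per library, given at the start of the results, set the precision: a library with few cells of a class gives a wide error for that class, and a fold against a group at 0 counts is given as a bound against a floor of 3 counts over the group. Counting intervals are at 95 percent and cover counting error only.

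The fits were tested on simulated data, in which 200 genes of the real means and library sizes were changed by 2 or 4 fold. Of 2-fold changes, the share recovered was 94% for dura mature B cells by age, 93% for blood, 95% for dura against blood and 60% for the age by tissue term. It was 77% for pre-B cells of dura against marrow, 81% for marrow pre-B cells by age, 90% for T cells, 69% for macrophages, 93% for monocytes, 94% for neutrophils and 81% for fibroblasts. Of 4-fold changes, 95% or more were recovered in each. The alternatives were DESeq2 1.42.0, no TMM, no filter on low counts, at least 50 cells per library, a UMI minimum of 1000, doublets kept, genes over 25 percent from free RNA left out, no batch term, each batch alone, the replicate number as a block, another denominator, permutation within batches, and each library left out in turn. Mature B cells were also fitted without the ABC-like and B1-like clusters. A UMI minimum of 500 alone and a reclustering of B cells without the 64 genes that define the ABC-like cluster were added after seeing the data, as was counting as mature the immature-like cluster 5, which had scores of 0.25 for immature and 0.34 for marginal zone B cells. Figures were drawn with matplotlib 3.10.9.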

Results

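Single-cell transcriptomes were collected from 3 tissues of young and aged mice in 33 libraries. There were 6 libraries of young blood, 7 of aged blood, 7 of young dura, 7 of aged dura, and 3 each of young and aged tibial marrow. The deposited matrices held 17654736 to 99139568 UMIs per library in young blood and 18989559 to 136090851 in aged blood. Dura libraries were shallower, with 4502464 to 12828030 UMIs in young and 6486170 to 21828052 in aged mice, and marrow libraries held 27741427 to 45977365. After filtering, 76873 and 64292 cells were kept from young and aged blood, 11743 and 26113 from young and aged dura, and 18415 and 20372 from young and aged marrow. Single dura libraries gave 1003 to 6025 cells. The median depth of a kept cell ran from 936.5 UMIs, in aged dura library 3, to 6934 UMIs in 1 aged blood library.

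The first question was in which tissue B cells at developmental stages are found. In the dura a large part of B lineage cells was at developing stages, while in blood nearly all were past them. Developing stages made up 59.4% ± 7.33 (SD, n = 7) of B lineage cells in young dura and 2.95% ± 1.54 (n = 6) in young blood. In aged mice they made up 60.6% ± 14.6 (n = 7) in dura and 4.04% ± 6.02 (n = 7) in blood. Pro-B-like cells, led by the surrogate light chain genes Vpreb1 and Igll1 and by Dntt of V(D)J joining, formed 2.01% ± 1.37 of young dura B cells and 0.0131% of young blood B cells. Cycling pre-B-like cells, led by histone genes, Top2a and Mki67, formed 6.24% ± 2.97 against 0.0397%, and resting pre-B-like cells 19.2% ± 5.70 against 0.171%. Immature-like cells, the stage at which the receptor first reaches the surface, formed 32.0% ± 6.17 against 2.73% ± 1.56. The aged libraries showed the same order. Pro-B-like cells formed 1.49% of dura B cells, and 0 of 26327 B cells of blood, which allows a share of up to 0.0114%. Means were 8.92% against 0.0323% for cycling pre-B-like, 24.4% against 0.263% for pre-B-like and 25.8% against 3.74% for immature-like cells. All 10 differences passed in exact two-sided permutation tests (young pro-B-like cells not in pairs by number, adjusted 0.0625). Adjusted exact p-values were 0.00146 for the young libraries other than pro-B-like (0.00816) and 0.000728 for the aged libraries other than immature-like (0.00117). Each of the dura libraries exceeded the blood median for the sum of developing stages. The lowest young dura library stood at 47.6% and the lowest aged one at 49.3%, above the highest aged blood library at 17.7%. The UMI minimum was above 500 in the 6 blood libraries of batch 1 and at 500 in every dura library. With 500 alone in all libraries, an alternative chosen after seeing the data, the same 10 differences passed. They also passed with immature-like cluster 5, which scored higher for marginal zone B cells, counted as mature, another such alternative. Developing stages were then 44.7% ± 9.42 in young and 47.7% ± 16.7 in aged dura, against 1.07% and 1.35% in blood.

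**Figure D1:**
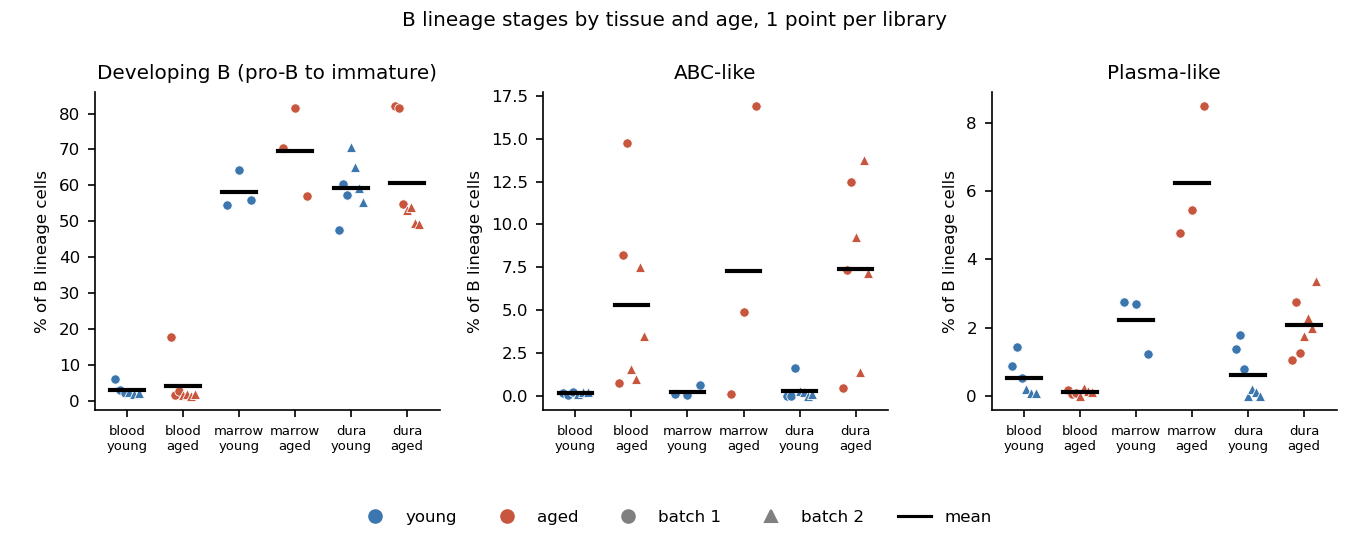
Shares of B lineage cells (percent, vertical axis) at developing stages (pro-B-like to immature-like), in ABC-like (age-associated B cell-like) and in plasma-like clusters, in the 6 groups of tissue and age; each point is a library (circles batch 1, triangles batch 2; blue young, red aged) and the black line is the group mean. Every dura and marrow library lies above every blood library for developing stages, and the mean of ABC-like cells is higher in aged than in young mice.

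Dura was set against marrow, the main site of B cell development in adult mice, within batch 1, the only batch with marrow libraries (3 against 3, smallest exact p of 0.1). In young mice the sum of developing stages was close, at 55.1% ± 6.70 in dura and 58.3% ± 5.28 in marrow (n = 3 each, exact p = 0.6). Immature-like cells formed 34.6% ± 5.36 of dura and 15.1% ± 3.34 of marrow B cells. Lower in dura were cycling pre-B-like cells, at 4.26% ± 3.11 against 11.8% ± 1.06, and pre-B-like cells, at 15.5% ± 6.52 against 29.0% ± 1.92. These 3 stages did not overlap between the tissues (exact p = 0.1, adjusted 0.167 over 5 tests, 10% of classes separating by chance). Pro-B-like cells formed 0.732% in dura and 2.46% in marrow (exact p = 0.2). In aged mice developing stages summed to 72.8% ± 15.7 in dura and 69.6% ± 12.3 in marrow, and only pro-B-like cells did not overlap, at 1.67% ± 0.263 against 3.81% ± 0.646 (exact p = 0.1, adjusted 0.5). Immature-like cells of blood and dura lay mainly in cluster 5, led by Cfp, Ccnd2 and Klhl14 (70.5% and 51.8% of them). Of those of marrow 67.2% lay in a cluster led by Dusp10 and Emid1, which held 32.9% of those of dura. With cluster 5 counted as mature, young immature-like cells formed 21.4% and 12.6% and overlapped (exact p = 0.2), and the sums differed by -13.96 points in young and -3.60 in aged mice. The direction of the young sum turned to 0.581 points higher in dura without young dura library 1. That of the aged sum turned to -1.39, -1.21 and -3.11 points without aged dura libraries 1 and 2 and aged marrow library 3, in that order.

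Few genes were called between pre-B-like cells of dura and marrow. Of 7160 genes 9 differed, 2 higher and 7 lower in dura (5 dura and 6 marrow libraries, ages together). Rab4b, a small GTPase of endosome recycling (ENSMUSG00000053291, chromosome 7, 27168424 to 27178896, GRCm38), was higher in dura at 100 CPM ± 19.9 against 45.8 ± 7.42 (log2 fold change 1.03 ± 0.20, adjusted p = 0.00665, higher in 5 of 5 libraries). Prg3, a granule protein gene of eosinophils and their precursors, was lower by -1.39 ± 0.22 (adjusted p = 0.000637). Plac8, a gene of immature and myeloid cells, was lower by -0.81 ± 0.15 (adjusted p = 0.00665), and both were lower in all 5 dura libraries than the marrow median. Rps27rt, a retrogene copy of Rps27 that can share reads with it and is therefore uncertain (chromosome 9, 114982366 to 114982739), was lower by -1.24 ± 0.20. Ribosomal protein genes Rpl41 (-0.57 ± 0.11) and Rplp2 (-0.53 ± 0.11) were lower too, each with an adjusted p of 0.00979. Of 91 ribosomal protein genes 3 fell, and 23 fell when adjusted over the list alone. The median of the list was -0.12 (camera adjusted p = 0.0109, and adjusted p = 0.788 with an estimated correlation). The other 11 lists had camera adjusted p-values of 0.0677 to 0.999. Ighg2b, the constant region of an IgG isotype, counted 2 UMIs in dura and 145 in marrow pre-B-like cells, a ratio of 19.0 (interval 5.17 to 159). Of the 145, 99 came from aged marrow library 1. The calls outside the naming rule, Ighv10-3 (4.43) and the gene model Gm10076, were looked up after their values were seen. DESeq2 called 52 genes. The edgeR count moved to 4 without aged marrow library 1, 5 without aged marrow library 2, 5 without young dura library 3, 64 without aged dura library 1 and 21 without aged dura library 3.

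The next question was how leukocyte classes of each tissue differ with age. In the dura, aged mice had fewer natural killer (NK)-like and dendritic-like cells and more basophil-like, haematopoietic stem and progenitor (HSPC)-like and plasma-like cells. NK-like cells formed 1.21% ± 0.533 of leukocytes in aged and 4.32% ± 2.10 in young dura (n = 7 each, exact p = 0.00117, adjusted 0.0140 over 12 classes), below the young median in 7 of 7 aged libraries. Basophil-like cells formed 1.28% ± 0.445 against 0.550% ± 0.226 (adjusted exact p = 0.0140, higher in 6 of 7), HSPC-like cells 1.01% ± 0.269 against 0.586% ± 0.0974 (adjusted exact p = 0.0140, higher in 7 of 7). Plasma-like cells formed 0.544% ± 0.201 against 0.170% ± 0.204 (adjusted exact p = 0.0192, higher in 7 of 7). Dendritic-like cells formed 1.11% ± 0.760 against 2.34% ± 0.910 (adjusted exact p = 0.0462, lower in 6 of 7). The difference had the same sign in each batch for all 5. In batches 1 and 2 it was -4.54 and -2.03 points for NK-like, 0.618 and 0.810 for basophil-like, 0.520 and 0.352 for HSPC-like, 0.0240 and 0.638 for plasma-like and -1.14 and -1.31 for dendritic-like cells. The plasma-like call was lost with same-numbered libraries as pairs (adjusted exact p = 0.107). The dendritic call was lost at a UMI minimum of 1000 (adjusted 0.0755), with all kept cells as the denominator (-0.968 points, adjusted 0.0944) and without any 1 of 11 libraries, all but aged library 4 and young libraries 1 and 2. Differences were then -0.981 to -1.26 points (adjusted exact p over all omissions 0.0168 to 0.0923).

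The other 7 dura classes did not pass. Neutrophil-like cells, the most frequent, formed 40.1% ± 9.24 of aged and 32.0% ± 6.60 of young dura leukocytes (adjusted exact p = 0.118). They passed with all kept cells as the denominator (10.9 points, adjusted 0.0392) and without aged library 4 (10.9 points, adjusted 0.0300). B lineage cells formed 28.1% ± 9.85 and 34.7% ± 9.64 (adjusted exact p = 0.268), with differences of 1.14 points in batch 1 and -12.5 in batch 2. T-like cells formed 7.67% ± 3.20 and 9.55% ± 5.17 (adjusted exact p = 0.456), with differences of -7.29 and 2.17 in the batches. Macrophage-like cells formed 1.57% ± 1.02 and 3.22% ± 1.61 (adjusted exact p = 0.0851), and monocyte-like cells 8.75% ± 3.77 and 6.13% ± 3.22 (adjusted exact p = 0.247).

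**Figure D2:**
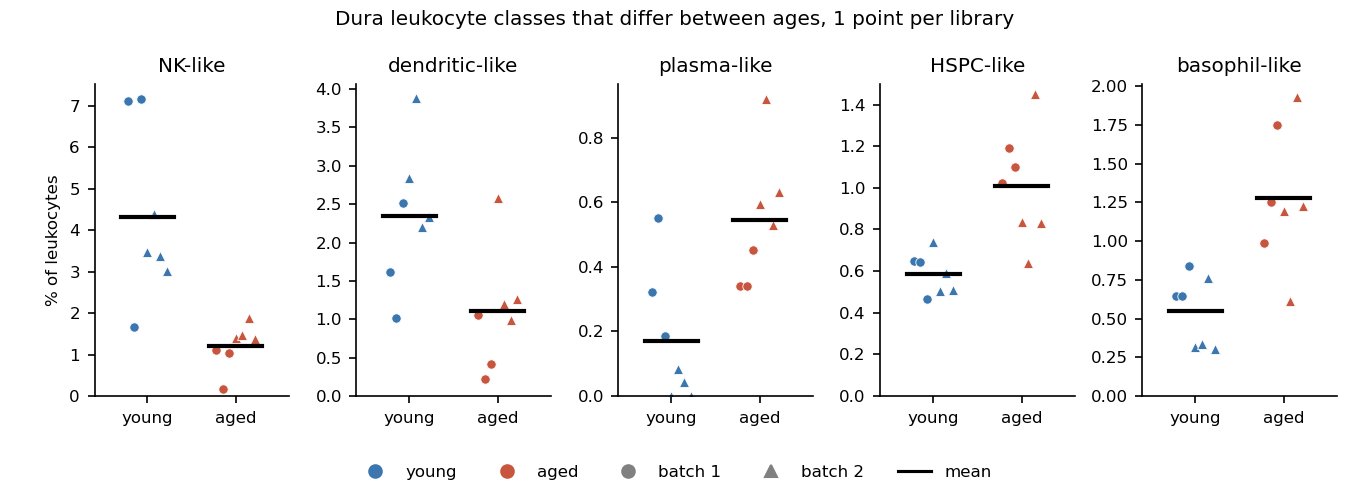
Shares of dura leukocytes (percent, vertical axis) by class in young (blue) and aged (red) mice; each point is a library (circles batch 1, triangles batch 2) and the black line is the mean of 7 libraries. NK-like cells are below the young median in all 7 aged libraries, and HSPC-like and plasma-like cells are above it in all 7.

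In blood, NK-like cells were the class that differed, at 2.28% ± 1.33 in aged (n = 7) and 7.01% ± 2.09 in young mice (n = 6; exact p = 0.00233, adjusted 0.0256 over 11 classes), lower in 7 of 7 aged libraries. The differences were -3.12 points in batch 1 and -6.15 in batch 2. The adjusted exact p was 0.0556 without any 1 of young libraries 1, 3, 4, 6 and 7, with differences of -4.45, -4.88, -4.18, -4.57 and -4.92 points. In same-numbered pairs, too few to decide, it was 0.172. T-like cells formed 10.0% ± 5.23 in aged and 17.6% ± 5.50 in young blood (adjusted exact p = 0.0994). Monocyte-like cells formed 17.7% ± 6.10 and 10.3% ± 1.95 (adjusted 0.0962), and B lineage cells 48.6% ± 15.4 and 51.1% ± 5.39 (adjusted 0.788). The monocyte difference passed without aged library 4 (9.47 points, adjusted exact p = 0.0119). In marrow the aged and young libraries did not overlap for T-like cells, 4.43% ± 1.29 against 2.37% ± 0.157, and macrophage-like cells, 3.15% ± 1.96 against 0.575% ± 0.138 (n = 3 each, exact p = 0.1, adjusted 0.6, with 10% of classes separating by chance). The age difference in dura minus that in blood passed its permutation test for plasma-like cells, with 0.375 points in dura and -0.232 in blood (difference 0.606, adjusted permutation p = 0.00418 over 11 tests). The blood part was -0.467 points in batch 1 and 0.00206 in batch 2. It also passed for dendritic-like cells, at -1.24 and 0.2495 points (difference -1.49, adjusted permutation p = 0.0247). The null of this test is no age effect in either tissue, and ages were permuted across batches, so passing does not by itself show unequal effects.

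Within the B lineage, age-associated B cell (ABC)-like cells, a class that accumulates in old mice, were rare in young mice and on average more frequent in aged ones. They formed 7.41% ± 5.07 of aged and 0.316% ± 0.577 of young dura B cells (n = 7 each, adjusted exact p = 0.00699 over 4 stages, 7 of 7 aged libraries higher). In blood they formed 5.32% ± 5.16 of aged (n = 7) and 0.169% ± 0.0563 of young B cells (n = 6, adjusted exact p = 0.00466, 7 of 7). The clusters were drawn partly by the genes that define them. A clustering without 64 such genes, added after seeing the data, gave 1 cluster with 62.2% of the ABC-like cells. Differences were then 4.69 points in dura (adjusted exact p = 0.0160) and 3.81 in blood (adjusted 0.0280). B1-like cells formed 1.71% ± 1.01 of aged and 0.487% ± 0.525 of young dura B cells (adjusted exact p = 0.0171, 7 of 7), and plasma-like cells 2.07% ± 0.821 and 0.614% ± 0.729 (adjusted 0.0128, 7 of 7). Developing stages in the dura did not differ by age over both batches (60.6% and 59.4%, adjusted exact p = 0.839). The batches went opposite ways, with 17.7 points more in aged dura in batch 1 (exact p = 0.3) and a change of -11.1 points in batch 2 (exact p = 0.0286). In marrow, plasma-like cells formed 6.24% ± 1.98 of aged and 2.22% ± 0.861 of young B cells (n = 3 each, exact p = 0.1, adjusted 0.267, no overlap).

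In blood, B1-like cells averaged 14.1% ± 29.97 in aged and 1.71% ± 0.522 in young mice (adjusted exact p = 0.0233, 7 of 7 higher). In aged library 2 they formed 82.1% of B cells, and without it the difference was 1.08 points. The call was lost without young library 2 or 4 (12.4 and 12.3 points, adjusted exact p = 0.0505 each) and in the permutation within batches (adjusted 0.661). That test took the blood ABC-like call to adjusted exact p = 0.0514, and pairs by number, too few to decide, to 0.125. Plasma-like cells of blood formed 0.113% of aged and 0.538% of young B cells (adjusted exact p = 0.0793), and passed without young library 6 or 7 (-0.513 and -0.517 points, adjusted 0.0438 and 0.0404). For plasma-like cells the age difference was 1.45 points in dura and -0.425 in blood (difference 1.88, adjusted permutation p = 0.00260 over 4 tests, with the same null as above). It was 0.360 and 2.27 points in batches 1 and 2 of dura and -0.852 and -0.00141 in those of blood, so the fall in blood was in batch 1. For ABC-like cells the difference between tissues did not pass (1.94, adjusted 0.978).

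Mature B cells of the dura, which include the ABC-like cluster whose share rose, had more transcript of ABC genes in aged mice. The list test below is thus not independent of that share. Of 5763 genes 63 rose and 15 fell in aged dura (14 libraries, 34 to 685 cells each). Zbtb20, a zinc finger repressor of plasma and memory B cells (ENSMUSG00000022708, chromosome 16, 42875881 to 43642602), was at 310 CPM ± 115 in aged and 94.9 ± 32.8 in young dura (log2 fold change 1.75 ± 0.24, adjusted p = 0.00108). Fcrl5, a receptor of the Fc receptor-like family (ENSMUSG00000048031, chromosome 3, 87435773 to 87500678), was at 91.9 CPM ± 49.4 against 22.2 ± 11.5 (2.09 ± 0.44, adjusted p = 0.0367). Cd300lf, an inhibitory myeloid receptor (ENSMUSG00000047798, chromosome 11, 115116214 to 115133992), was at 32.5 CPM ± 9.62 against 3.09 ± 3.33 (3.44 ± 0.45, adjusted p = 2.77e-05). Of the 7 measured genes of the ABC list 5 rose. They were Zbtb20, Fcrl5, Zbtb32 (2.66 ± 0.58, adjusted p = 0.0462), the scaffold gene Ahnak (1.77 ± 0.35, adjusted p = 0.0292) and the repressor Zeb2 (0.80 ± 0.19, adjusted p = 0.0373). All 7 rose when adjusted over the list alone (camera adjusted p = 1.25e-13, and adjusted p = 0.0210 with an estimated correlation). Among its members, Fcer1g, the Fc receptor gamma chain, had a change of 4.08 ± 0.99 with an adjusted p of 0.0748. Other genes with large rises encode the fibrinogen-like Fgl2 (4.68 ± 1.01), the macrophage antigen Adgre1 (4.02 ± 0.68), the calcium channel Cacna1s (4.01 ± 0.68), the integrin Itgb1 (2.49 ± 0.42), Rcn3 (2.42 ± 0.54), Plscr1 (2.41 ± 0.47), Sirpa (2.36 ± 0.44) and Aldh3b1 (2.35 ± 0.32). Their adjusted p-values ran from 5.27e-05 (Aldh3b1) to 0.0491 (Fgl2). Each of the genes named so far was higher in 7 of 7 aged libraries than the young median. Ighm, the IgM constant region, rose by 0.76 ± 0.16 (adjusted p = 0.00702, 6 of 7 libraries).

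The genes that fell in aged dura B cells changed less. S1pr4, a sphingosine phosphate receptor of lymphocytes, changed by -0.66 ± 0.13 (adjusted p = 0.00399), Ccr7, the chemokine receptor for entry into lymph nodes, by -0.58 ± 0.13 (adjusted p = 0.0150). Tmem108 changed by -1.05 ± 0.19 (adjusted p = 0.00179) and Serpinb1a by -0.76 ± 0.15 (adjusted p = 0.00307). Ell3 (-1.09), Sufu (-0.93), Cpm (-0.73) and Rflnb (-1.32) fell as well. Serpinb1a, Pkib (-0.74), Cnn3 (-0.73) and B3gnt8 (-0.72) are among the leading genes of cluster 3, which held 37.6% of mature B cells in young and 29.3% in aged dura, counted over cells. The named falling genes were lower in 7 of 7 aged libraries than the young median, other than Rflnb in 6 of 7. Of 8 follicular B cell genes 1 fell, Ccr7. When adjusted over the list alone 3 fell and 1 rose (median -0.51, camera adjusted p = 0.000394, and adjusted p = 0.349 with an estimated correlation). Fcer2a, the low affinity IgE receptor of follicular B cells, had a change of -0.995 ± 0.295 (adjusted p = 0.154). None of 10 MHC class II genes (median 0.24, 2 rose when adjusted over the list alone) and none of 78 oxidative phosphorylation genes (median 0.11, 0 over the list alone) passed. Their camera adjusted p-values of 0.0179 and 0.000158 became 0.452 each as adjusted p with an estimated correlation. The other 6 lists had camera adjusted p-values of 0.0725 to 0.976.

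Without the ABC-like and B1-like clusters 3 genes were called in dura mature B cells over 13 libraries (aged library 2 kept 15 cells, and without it alone the count was 79), all higher in aged mice and all among the 78. Of the genes named, Ighm kept its call (0.755). Zbtb20 (0.373), Ahnak (0.566) and Itgb1 (0.605) lost theirs with a smaller change, and Ccr7 (-0.451), S1pr4 (-0.469) and Ell3 (-0.725) lost theirs with more of the change left, unlike Cpm (-0.249) and Pkib (-0.314). Batch 1 alone called 2 genes and batch 2 alone 47. The count was 49 without young library 5, 42 without young library 6, 153 without aged library 1, 45 without aged library 4, 131 without aged library 5, 33 without aged library 6 and 50 without aged library 7.

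**Figure D3:**
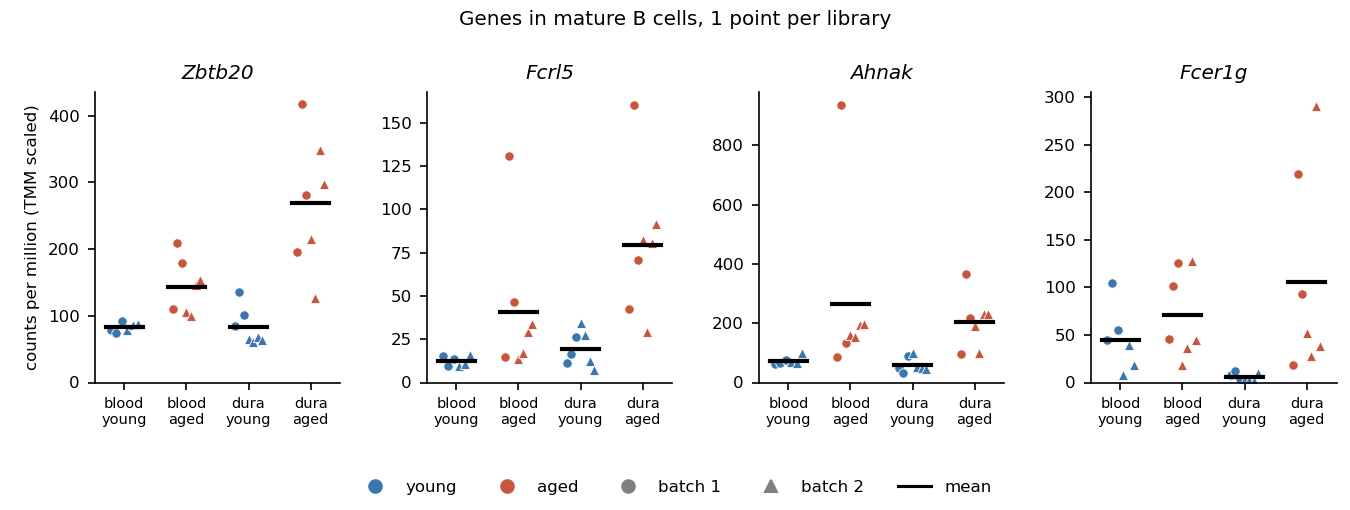
Expression of Zbtb20, Fcrl5, Ahnak and Fcer1g in mature B cells (CPM, vertical axis, scaled over both tissues together, so that levels differ from those of each tissue's own fit) of blood and dura by age; each point is a library (circles batch 1, triangles batch 2; blue young, red aged) and the black line is the group mean. In dura all 7 aged libraries lie above the young median for each gene, and the Fcer1g change did not pass the test.

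In blood mature B cells, 29 of 10903 genes rose and 4 fell with age (13 libraries). They include 4 genes of the ABC list, Itgam, Ighg2c, Tbx21 and Cxcr3. Fgl2 (ENSMUSG00000039899, chromosome 5, 21372642 to 21378374) was at 21.8 CPM ± 25.7 in aged and 1.58 ± 0.451 in young blood (3.82 ± 0.66, adjusted p = 0.0345), with 76.9 CPM in aged library 2. Tbx21, the transcription factor T-bet, changed by 2.38 ± 0.45 (adjusted p = 0.0456) and Itgam by 3.14 ± 0.55 (adjusted p = 0.0314). Ighg2c changed by 3.12 ± 0.55 (adjusted p = 0.0298), Cxcr3 by 2.15 ± 0.42 (adjusted p = 0.0471) and Il9r by 1.33 ± 0.23 (adjusted p = 0.0298). All 6 were higher in 7 of 7 aged libraries. Tbx21, Itgam and Ighg2c reached 6.38, 6.28 and 2.68 CPM in aged libraries other than 2. Without aged library 2 the changes were 3.04 for Fgl2, 2.27 for Itgam, 2.58 for Ighg2c and 1.89 for Tbx21 (adjusted p = 0.0641). Free RNA could account for 19.7% of Fgl2 and 24.5% of Itgam counts in young and 1.91% and 3.73% in aged blood. Of 15 ABC genes 4 rose, 14 when adjusted over the list alone (median 2.15, camera adjusted p = 2.34e-21, and adjusted p = 0.0637 with an estimated correlation). Zbtb32 (3.47 ± 0.76, adjusted p = 0.0887) and Zbtb20 (0.78 ± 0.16, adjusted p = 0.0546) did not pass. Of 7 isotype genes 1 rose, Ighg2c, and 3 when adjusted over the list alone (camera adjusted p = 0.00221, and 0.123 as adjusted p with an estimated correlation). Lists of follicular B cell (median -0.33), naive T (-0.43) and lipid-associated macrophage genes (0.60) had no called member, and 0, 2 and 3 when adjusted over the list alone. Their camera adjusted p-values of 0.0115, 0.00638 and 0.00845 became 0.736, 0.391 and 0.427 as adjusted p with an estimated correlation. The other 13 lists had camera adjusted p-values of 0.0682 to 0.862.

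Without the ABC-like and B1-like clusters 24 genes were called in blood, 12 of them among the 33 but only 1 of the 6 named above. With the replicate number as a block 43 genes were called, 15 of them among the 33 but 0 of the 6 named above. Batch 1 alone called 0 genes by edgeR (553 at an unadjusted p under 0.05) and batch 2 alone 116, and DESeq2 called 142. The count was 7, 7, 14, 15, 13 and 11 without young libraries 1, 2, 3, 4, 6 and 7 and 137, 109, 20, 16 and 15 without aged libraries 1, 2, 3, 6 and 7.

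Whether the age effect differed between dura and blood B cells was tested by the age by tissue term over 27 libraries. No gene of 8446 passed by edgeR, with 424 at an unadjusted p under 0.05, and DESeq2 called 0. The term was 0.95 ± 0.28 for Zbtb20 (adjusted p = 0.903) and 3.34 ± 1.19 for Fcer1g (adjusted p = 0.917), both larger rises in dura. Free RNA could account for 18.3% of the Fcer1g counts in blood. Of 11 ABC genes 0 passed and 1 when adjusted over the list alone, with a median term of 0.41 (camera adjusted p = 0.000451, and adjusted p = 0.388 with an estimated correlation). The other 15 lists had camera adjusted p-values of 0.0554 to 0.825. Without aged blood library 2 there was 1 call.

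Mature B cells of the dura differed from those of blood in 1377 of 8138 genes, 677 higher and 700 lower (14 dura and 13 blood libraries, ages and batches as terms). Dura cells had less MHC class II, trafficking receptor and immediate early transcript, and more of B cell receptor signalling genes. The class was also made up of clusters in other proportions in the 2 tissues, as given below. Of 10 MHC class II genes 9 fell, and 10 when adjusted over the list alone. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) was at 3836 CPM ± 1045 in dura against 5619 ± 450 in blood (-0.57 ± 0.09, adjusted p = 3.02e-05), and H2-Eb1 changed by -0.51 ± 0.09 (adjusted p = 0.000132). The camera adjusted p was 8.36e-08, and the adjusted p with an estimated correlation 0.0373. Of 14 trafficking genes 8 fell, and 8 when adjusted over the list alone (camera adjusted p = 6.82e-05, and 0.0167 as adjusted p with an estimated correlation). They include Cxcr5, the receptor that guides B cells to follicles (ENSMUSG00000047880, chromosome 9, 44511787 to 44561877), at 68.9 CPM ± 25.5 in dura against 136 ± 37.3 in blood (-1.0001 ± 0.12, adjusted p = 2.78e-07). The others include the integrin Itgb7 (-0.81 ± 0.16), Ccr7 (-0.74 ± 0.15) and Gpr183 (-0.74 ± 0.13), each lower in 13 or 14 of 14 dura libraries than the blood median. Of 14 immediate early and heat shock genes 7 fell and 1 rose, and 9 and 2 when adjusted over the list alone. They include Junb at -0.91 ± 0.10 (adjusted p = 4.15e-08) and Klf6 at -0.89 ± 0.12 (adjusted p = 1.33e-06), both lower in 14 of 14 libraries (camera adjusted p = 0.000963, and 0.0373 as adjusted p with an estimated correlation). Of 8 follicular genes 6 fell, also when adjusted over the list alone, among them Fcer2a (-0.996 ± 0.258, adjusted p = 0.00829). The camera adjusted p was 0.00171, and the adjusted p with an estimated correlation 0.256. Of 6 naive T list genes 3 fell, and 4 over the list alone, with Ccr7 among the shared members (camera adjusted p = 0.00903, and adjusted p = 0.0789 with an estimated correlation).

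Of 17 B cell receptor signalling genes 8 were higher in dura, also when adjusted over the list alone, where 1 fell (camera adjusted p = 0.000152, and 0.0167 as adjusted p with an estimated correlation). Cd72, an inhibitory coreceptor, was at 467 CPM ± 133 in dura against 229 ± 43.7 in blood (1.01 ± 0.11, adjusted p = 6.01e-08, 14 of 14 libraries), and the adaptor Pik3ap1 changed by 0.87 ± 0.16 (adjusted p = 0.000178, 12 of 14). Of 6 V(D)J recombination and pre-B receptor genes 4 were higher, and 4 when adjusted over the list alone (camera adjusted p = 0.00557, and 0.0214 as adjusted p with an estimated correlation). Vpreb3, a chaperone of the pre-B receptor, was at 913 CPM ± 394 against 404 ± 159 (1.14 ± 0.27, adjusted p = 0.00414, 13 of 14). Among genes named for their size, Coq7 (ENSMUSG00000030652, chromosome 7, 118509659 to 118533356) was at 63.3 CPM ± 25.1 against 17.0 ± 6.39 (1.96 ± 0.22, adjusted p = 4.03e-07, 14 of 14). Others were Akap12 (1.90), Cplx2 (1.87), Bhlhe40 (1.86), Mir142hg (1.85), Myl4 (1.82) and Dusp10 (1.77). Dusp10 and Cd72 also lead immature-like cluster 16. An effect of stage was not tested. Ighm (0.41 ± 0.13, adjusted p = 0.0236, 10 of 14) and Zeb2 (0.87 ± 0.13, 13 of 14) were also higher. Of the named genes called, 32 of 33 kept their call with any 1 library left out, and Ighm lost it without aged dura library 1.

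RNA of other cell types moved with the tissue. Red cell and platelet genes were lower in dura, with 6 of 6 measured members of each list, also when adjusted over the list alone. Their camera adjusted p-values were 2.62e-23 and 5.32e-28, and their adjusted p-values with an estimated correlation 3.42e-05 and 0.000118. Alas2, of haem synthesis in red cells, had 1 count in dura and 106818 in blood B cells (ratio 5751, interval 1032 to 2.27e+05). The platelet chemokine Ppbp had 2 and 41255 counts (ratio 1111, interval 307 to 9171), and Gng11 had 2 and 46936 counts (ratio 1264, interval 350 to 10433). Against a floor of 3 counts over the dura libraries, Itga2b was at least 162-fold lower in dura, Alox12 150-fold, Tubb1 141-fold, Gp1bb 108-fold, Treml1 67.9-fold and Vwf 52.0-fold. Neutrophil granule genes were higher in dura B cells for 5 of 6 members, also when adjusted over the list alone (camera adjusted p = 9.28e-07, and 0.0214 as adjusted p with an estimated correlation), with Ngp at 4.15 ± 0.53 and Camp at 3.67 ± 0.47. Free RNA could account for 28.0% and 35.4% of their counts in dura and 89.2% and 76.5% in blood.

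Scaling moved the split of calls. Without TMM 3498 genes were higher and 245 lower in dura, and the median of all genes was 0.28 in place of 0.01. The changes given are relative to that median. Without TMM the medians of MHC class II (-0.47, then -0.19), trafficking (-0.58, then -0.31) and immediate early genes (-0.36, then -0.08) kept their sign. That of 93 ribosomal protein genes, of which 56 fell and 1 rose (63 and 6 when adjusted over the list alone), went from -0.28 to 0.00094, and that of 83 oxidative phosphorylation genes (9 fell, 1 rose, 5 and 1 over the list alone) from -0.13 to 0.15. These 2 lists had camera adjusted p-values of 1.11e-12 and 0.0035, and 0.216 and 0.501 with an estimated correlation. The other 4 had camera adjusted p-values of 0.0834 to 0.735. Rps24 was at -0.56 ± 0.08 (adjusted p = 8.88e-06). In dura 32.3% of mature B cells, and in blood 6.71%, lay in cluster 3, led by Wfdc21, B3gnt8 and Cnn3. Of dura cells 6.92%, 1.94% and 4.66% lay in clusters 0, 1 and 2, led by Fcer2a and Ighd, and 11.6% in the ABC-like cluster. Clusters 0 to 2 held 15.1%, 11.0% and 7.99% in blood. Batch 1 alone called 272 genes, 50 higher and 222 lower. There MHC class II and trafficking lists had camera adjusted p-values of 0.0875 and 0.121.

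In marrow, pre-B-like cells of aged mice carried more MHC class II transcript. Of 6988 genes 12 rose and 3 fell (3 libraries against 3, 1 batch). Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), was at 1226 CPM ± 241 in aged and 610 ± 83.6 in young marrow (0.99 ± 0.13, adjusted p = 0.000121). H2-Eb1 changed by 1.26 ± 0.19 (adjusted p = 0.000121), H2-Aa by 0.91 ± 0.14 (adjusted p = 0.000266) and H2-Ab1 by 0.75 ± 0.16 (adjusted p = 0.0198). These were the 4 of 8 MHC class II genes that rose, and the 4 when adjusted over the list alone (camera adjusted p = 1.18e-06, and adjusted p = 0.534 with an estimated correlation). Ighg2b rose by 4.75 ± 0.68 (adjusted p = 0.0162), and free RNA could account for 37.5% of its counts in young and 4.67% in aged marrow. Emc4 (1.23), Sp140 (0.93), Pik3ap1 (0.80) and Prg3 (0.75) rose too. N4bp2 (-0.92 ± 0.15, adjusted p = 0.000438), Col5a3 (-0.85) and Reln (-0.65) fell. Each named gene went its way in 3 of 3 aged libraries against the young median. Interferon response (0 of 8 genes, 2 over the list alone, median 0.41), oxidative phosphorylation (0 of 78, 0 over the list alone, median 0.17) and ribosomal protein genes (0 of 92, 8 higher and 1 lower over the list alone, median 0.11) had no called member. Their camera adjusted p-values were 0.000918, 9.2e-06 and 0.0197, and their adjusted p-values 0.637, 0.637 and 0.742 with an estimated correlation. The other 7 lists had camera adjusted p-values of 0.0891 to 0.721. DESeq2 called 7 genes. The edgeR count was 39 without young library 2, 6 without young library 3, 37 without aged library 1 and 7 without aged library 3.

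Among the other classes of the dura, T-like cells changed most with age, from naive toward effector and memory genes. Of 5704 genes 147 rose and 92 fell (7 against 7 libraries). Eomes, a transcription factor of effector and memory T cells (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), was at 171 CPM ± 50.3 in aged and 47.8 ± 16.0 in young dura (1.89 ± 0.18, adjusted p = 4.31e-10). The granzyme Gzmk was at 377 CPM ± 196 against 75.1 ± 68.7 (2.41 ± 0.51, adjusted p = 0.0214). The inhibitory receptors Lag3 (2.35 ± 0.36), Tigit (2.12 ± 0.39) and Pdcd1 (1.09 ± 0.19) rose, with adjusted p-values of 0.000673, 0.00899 and 0.000215, as did Ier3 (2.08 ± 0.30) and Nkg7 (0.84 ± 0.13). Of 13 effector and memory genes 8 rose and 1 fell, also when adjusted over the list alone (median 1.04, camera adjusted p = 1.38e-07, and adjusted p = 0.0548 with an estimated correlation). Lef1, a transcription factor of naive T cells (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), was at 87.9 CPM ± 34.8 against 272 ± 88.6 (-1.71 ± 0.17, adjusted p = 4.01e-08). With it 6 of 9 naive T genes fell, 7 when adjusted over the list alone (median -1.18, camera adjusted p = 3.34e-11, and 0.0405 as adjusted p with an estimated correlation). They include Dapl1 (-2.87 ± 0.28, adjusted p = 4.51e-09), Ccr7 (-1.79 ± 0.36, adjusted p = 0.00971) and Klf2 (-0.92 ± 0.15, adjusted p = 0.000448). Ly6c1 fell by 3.72 on the log2 scale (± 0.34, adjusted p = 2.58e-10), though its near-identical neighbour Ly6c2 can share its reads, and Igfbp4 (-3.45 ± 0.34) and Dtx1 (-1.90 ± 0.26) fell with it. Every rising gene named was higher, and every falling one lower, in 7 of 7 aged libraries than the young median.

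Of 18 interferon response genes 1 rose in T-like cells, Gbp2 (0.60 ± 0.18, adjusted p = 0.0450), and 4 when adjusted over the list alone (camera adjusted p = 0.000145). Of 14 NF-kB targets 1 rose, Tnfaip3 (0.81 ± 0.21, adjusted p = 0.0141), and 2 over the list alone (camera adjusted p = 0.0338). With an estimated correlation the adjusted p of both lists was 0.283. Igkc, the kappa light chain of B cells, was higher by 2.55 ± 0.59 (adjusted p = 0.0329) in aged T-like cells, and free RNA could account for 3.16% of its counts in aged and 12.7% in young dura. The other 8 lists had camera adjusted p-values of 0.138 to 0.685. Batch 1 alone called 38 genes and batch 2 alone 145, and no single library moved the count by over 1.5 times.

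Macrophage-like cells of the dura had less of the genes of resident border macrophages in aged mice. Of 3966 genes 10 rose and 19 fell (11 libraries with at least 20 such cells). Mrc1, the mannose receptor CD206 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), was at 952 CPM ± 177 in aged and 1465 ± 66.5 in young dura (-0.60 ± 0.14, adjusted p = 0.0129). Of 10 resident genes 5 fell, with Pf4 (-0.73 ± 0.15), Cbr2 (-0.84 ± 0.18) and Folr2 (-0.91 ± 0.20) among them. When adjusted over the list alone 7 fell (median -0.81, camera adjusted p = 2.16e-11, and adjusted p = 0.184 with an estimated correlation). Ccl24 (-1.57 ± 0.33, adjusted p = 0.0137), Gstm1 (-1.46 ± 0.30, of a family of similar genes), Ptgs1 (-1.03 ± 0.25) and Fcgrt (-1.01 ± 0.19) fell too. The interferon-induced Ifi44 (2.34 ± 0.45, adjusted p = 0.00227, 6 of 6) and Ifi213 (1.06 ± 0.27, adjusted p = 0.0340, 5 of 6), Gdf3 (1.36 ± 0.30), Top2a (2.22 ± 0.57) and Mfsd14b (1.40 ± 0.36) rose. The named falling genes were lower in 6 of 6 aged libraries than the young median, other than Ccl24 in 5. Retnla, of alternatively activated macrophages, counted 1 UMI over aged and 439 over young libraries, 377 of them in young library 3 (ratio 494, interval 88.2 to 19546).

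Lists of interferon response (0 of 19 genes, 4 higher and 1 lower over the list alone, median 0.29), MHC class II (0 of 8, 1 over the list alone, 0.27) and ribosomal protein genes (0 of 87, 0 over the list alone, 0.24) had no called member in macrophage-like cells. Their camera adjusted p-values were 0.000425, 0.00135 and 4.87e-13, and their adjusted p-values 0.540, 0.459 and 0.484 with an estimated correlation. Neutrophil genes, those of another cell type, were also higher, with a median of 5.24 over 7 members (0 called, 6 over the list alone). The camera adjusted p was 2.07e-07, and the adjusted p with an estimated correlation 0.329. An example is S100a9 at 5.68 ± 1.40 (adjusted p = 0.203), whose counts free RNA could account for to 3.66% in aged and 100% in young dura. The other 9 lists had camera adjusted p-values of 0.0548 to 0.706. The count was 16 at a UMI minimum of 1000, 19 with libraries of at least 50 cells, 14 in batch 2 alone, 13 without young library 3 and 18 without aged library 4. Batch 1 held too few libraries to be fitted alone.

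In monocyte-like cells 1 of 7999 genes passed. Oxidative phosphorylation (median 0.12) and neutrophil genes (0.90, with Ngp at 2.77 ± 1.26 and an adjusted p of 0.735) had no called member, also when adjusted over the list alone. Their camera adjusted p-values of 0.000334 and 0.0239 became 0.966 each as adjusted p with an estimated correlation. The other 11 lists had camera adjusted p-values of 0.0876 to 0.939. The count was 9 in batch 2 alone, and in batch 1 alone 0 by edgeR (176 at an unadjusted p under 0.05). It was 5 without young library 3, 7, 2, 3, 10 and 3 without aged libraries 1, 2, 3, 4 and 6, and 0 without young library 4, 5, 6 or 7 or aged library 7.

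In neutrophil-like cells 4 of 6431 genes rose and 3 fell. The calcium-binding S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181) was at 9342 CPM ± 1449.8 in aged and 6603 ± 710 in young dura (0.50 ± 0.10, adjusted p = 0.0138, 7 of 7). The receptor Bmpr1a rose by 0.93 ± 0.18 (adjusted p = 0.0260, 7 of 7) and the adenosine kinase Adk changed by -0.84 ± 0.18 (adjusted p = 0.0421, lower in 7 of 7). Outside the naming rule, and looked up after their values were seen, were Ces1d (1.63), C130026I21Rik (2.29), Mgp (-1.93) and Ppcdc (-0.75). None of 18 interferon response genes passed, and 1 when adjusted over the list alone. All 18 lay above 0 (median 0.66, with Ifi47 at 1.22 ± 0.31 and an adjusted p of 0.125). The camera adjusted p was 2.15e-09, against an adjusted p of 0.538 with an estimated correlation. The other 8 lists had camera adjusted p-values of 0.306 to 0.969. The count was 2 at a UMI minimum of 1000, 0 by edgeR in batch 1 alone (221 at an unadjusted p under 0.05), and 14 in batch 2 alone. It was 3, 2, 3 and 4 without young libraries 2, 4, 6 and 7, and 13, 24, 2 and 2 without aged libraries 1, 3, 6 and 7.

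Fibroblast-like cells of the dura lost extracellular matrix transcript with age. Of 2845 genes 2 rose and 11 fell (14 libraries, few cells each). Sparc, a matrix glycoprotein gene (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183), was at 1842 CPM ± 447 in aged and 3482 ± 854 in young dura (-0.92 ± 0.15, adjusted p = 0.00307). With the collagens Col3a1 (-0.90 ± 0.19, adjusted p = 0.0146) and Col1a1 (-0.68 ± 0.14, adjusted p = 0.0163) it made up the 3 of 14 matrix genes that fell. When adjusted over the list alone 8 fell (median -0.58, camera adjusted p = 4.91e-10, and 0.00716 as adjusted p with an estimated correlation). The cartilage protein Cilp2 (-2.49 ± 0.47), the cyclin Ccnd2 (-2.22 ± 0.39), the microfibril gene Mfap2 (-1.38 ± 0.25), the growth factor Igf2 (-1.37 ± 0.28) and Ubash3b (-1.36 ± 0.31) fell. Adjusted p-values ran from 0.00338 (Ccnd2) to 0.0367 (Ubash3b), and each was lower in 7 of 7 aged libraries against the young median. The immunoproteasome subunit Psmb8 (1.30 ± 0.28, adjusted p = 0.0181, 6 of 7) and S100a11 (0.86 ± 0.16, adjusted p = 0.00474, 7 of 7) rose. None of 6 MHC class II genes passed, 4 when adjusted over the list alone (median 0.95, with H2-Ab1 at 0.94 ± 0.23 and an adjusted p of 0.0712). The same held for 9 interferon response genes (2 over the list alone, median 0.62) and 76 oxidative phosphorylation genes (0 over the list alone, median 0.11).

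These 3 lists had camera adjusted p-values of 1.53e-06, 0.00412 and 0.00209 in fibroblast-like cells, and adjusted p-values of 0.104, 0.245 and 0.284 with an estimated correlation. Neutrophil genes were also higher, with a median of 2.38 over 10 members (0 called, 5 over the list alone). The camera adjusted p was 6.01e-09, and the adjusted p with an estimated correlation 0.135. An example is Ngp at 3.43 ± 1.17 (adjusted p = 0.294). The other 3 lists had camera adjusted p-values of 0.0947 to 0.472. Batch 1 alone called 7 genes and batch 2 alone 22, DESeq2 called 27 and 35 were called with doublets kept. The count was 21 without young library 3, 6 without young library 4, and 23, 28 and 20 without aged libraries 1, 2 and 4.

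**Figure D4:**
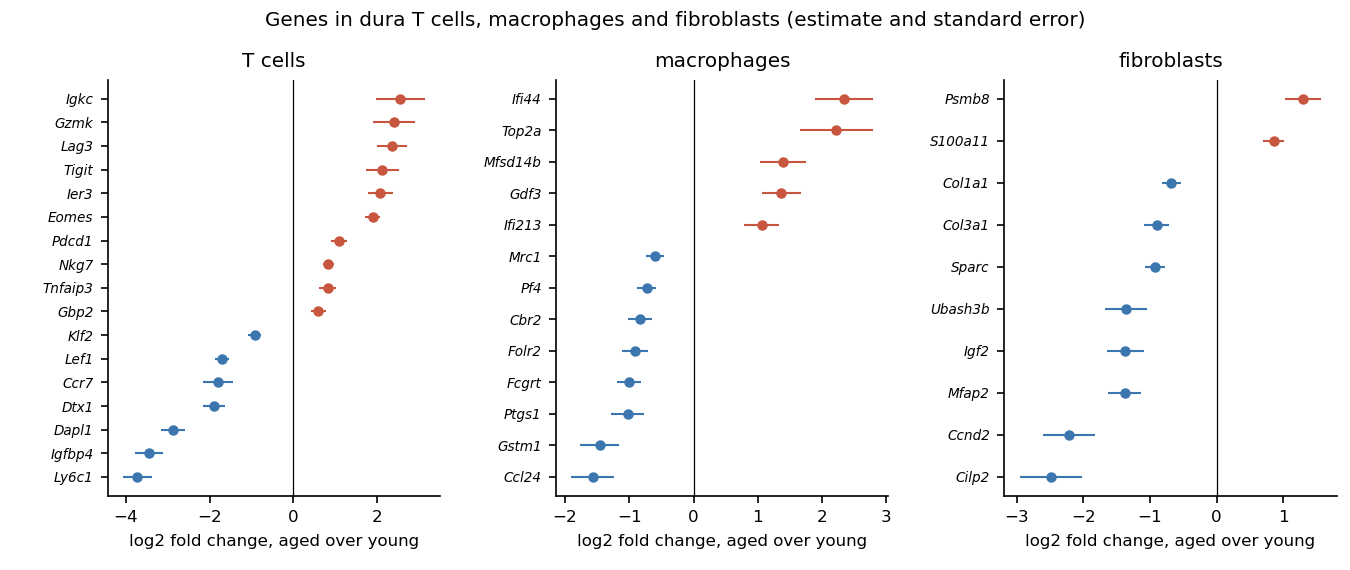
Log2 fold change in aged against young dura (horizontal axis) of the named genes in T-like, macrophage-like (Retnla left out) and fibroblast-like cells; points are edgeR estimates (red above 0, blue below) and bars are ± 1 SE. In T-like cells Eomes, Lag3 and Gzmk lie above 0 and Lef1 and Dapl1 below it, Mrc1 and Folr2 lie below 0 in macrophage-like cells, and Sparc, Col1a1 and Col3a1 below 0 in fibroblast-like cells.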

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

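The test of the UMI minimum and the V segments of B1-like cells in aged blood library 2 and the split counts of dura, blood and marrow B cells and of neutrophil-like cells were chosen only after the results were seen. A library far from the rest of its group was sought with the Dixon ratio, the gap to the nearest library over the range of the group. It passed in 54 of 367 groups, and chance passes about 1 in 20. Of these, 12 fell in aged dura library 2, the one with fewest mature B cells (34), and 11 in aged blood library 2.

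In aged dura library 2 the high values were those of Fgl2 (ratio 0.7133), Cacna1s (0.6893), Plscr1 (0.7196) and Ighg2b (0.5759) in mature B cells, Ngp (0.7618) and Junb (0.6383) in the same cells set against blood, Lag3 (0.5895), Tigit (0.6817) and Ier3 (0.8229) in T-like cells, and the shares of granulocyte progenitor-like (0.6809, 19.0% of leukocytes) and cycling pre-B-like cells (0.6188, 20.2% of B cells). Serpinb1a was low (0.6262). Aged dura library 3 had high Ighm (0.5904 by age, 0.5777 against blood), Igkc in T-like cells (0.6318) and Ngp in monocyte-like cells (0.6047). It was shallow like batch 2, and its empty barcodes held haemoglobin (10.5%) like batch 1. Young dura library 2 stood apart for Rflnb (0.6395), Ngp (0.8925) and Camp (0.9081) in mature B cells, Ngp in monocyte-like cells (0.8009) and Sparc (0.5714). Among other dura libraries, young library 1 stood apart for Cxcr5 (0.5994) and the T-like share (0.6108), young library 3 for Retnla (0.942) and the ABC-like share (0.8346), young library 5 for Ighg2b (0.6905) and young library 6 for Ifi44 (0.8298). Aged library 1 did so for Rflnb (0.6849), library 4 for the T-like share (0.661), library 6 for Ccl24 (0.7751) and library 7 for S100a9 in macrophage-like cells (0.9113).

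Aged blood library 1 had the highest developing share of blood (0.9141, 17.7% of B cells), with its cycling pre-B-like (0.5773), pre-B-like (0.6552) and immature-like parts (0.9044), and stood apart for Coq7 (0.6976) and Myl4 (0.6062). Young blood library 1 stood apart for the developing (0.7432) and immature-like shares (0.7213), library 2 for Tubb1 (0.7428), library 3 for the cycling pre-B-like share (0.8538) and library 4 for a low B lineage share (0.6269), and aged blood library 3 for Gng11 (0.6809). The age difference in dura minus that in blood passed for plasma-like cells, at 0.6064 points of leukocytes and 1.878 points of B cells, and for dendritic-like cells, at -1.487 points. The null of that test is no age effect in either tissue, so unequal effects are not shown by it alone.

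Aged blood library 2 held B1-like cells at 82.1% of its B cells (ratio 0.9685). Its mature B cells had high Fgl2 (0.673), Itgam (0.813), Ighg2c (0.6223), Tbx21 (0.5716), Zbtb32 (0.8785), Dusp10 (0.5915), Cxcr5 (0.7335) and Itgb7 (0.8921) and low Ccr7 (0.6058) and Fcer2a (0.7211). The library also held nearly all macrophage-like cells of blood. The higher UMI minimum of that library is argued against, since the B1-like share was 65.163% at 500 UMIs. Cells of the peritoneal cavity, where B1 cells and Gata6-dependent macrophages reside, remain as the explanation that fits, as all 9 listed peritoneal macrophage genes were at 2-fold or more over dura and marrow macrophage-like cells. Gata6 was at 53.3 CPM against 0 and 0, and Icam2 at 1020 against 9.04 and 17.0. V segments of its B1-like cells were led by Ighv1-52 (48.69%) and Ighv13-2 (21.34%), with an effective number of 3.418 over 1181 cells against 5.873 to 20.63 in the other aged blood libraries. Among 10 cells 4.427 segments were seen, against 6.215 to 8.746. Such narrow use would go with a B1-like expansion in that mouse, in blood or in the cavity alike, which stays open because a V segment is not a clonotype. How such cells could have reached a blood sample was not tested.

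Other splits of the same libraries into groups of the same sizes were fitted to ask whether chance alone gives as many genes. Among 100 splits the real one alone reached its count for dura mature B cells (78 genes, highest other 11), dura T-like cells (239, highest other 13), macrophage-like cells (29, highest other 20) and fibroblast-like cells (13, highest other 3), and among 60 for dura against blood (1377, highest other 17), so chance is unlikely. For blood mature B cells 3 of 100 splits reached 33 and another split called 99, for pre-B-like cells of dura against marrow 3 of 100 reached 9 and another called 37, and for neutrophil-like cells 3 of 100 reached 7 and another called 11. For blood mature B cells and dura against marrow, a split with several times the real count can point to a structure of the samples other than the groups. Chance stays open for monocyte-like cells, where 12 of 100 splits reached 1 gene and another called 5. For the interaction the real count was 0, which all 60 splits reach, so they say nothing on chance. For marrow pre-B-like cells 10 splits were too few (15 genes in the real one, highest other 3).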

How the results depend on the processing

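The UMI minimum of 500 alone, the clustering without the genes of ABC-like cells and cluster 5 counted as mature were chosen only after seeing the data. Of 3671 values of named genes under alternatives, 3142 kept direction and side of the threshold, 498 lost the call, 31 gained it and none reversed. Genes named by size had to keep direction in each batch. Of 935 share results 867 were kept. Depth and cell number limit the genes tested, 5763 in dura against 10903 in blood mature B cells by age. Dura library medians were 936.5 to 4226 UMIs per cell, and fibroblast-like and macrophage-like cells were few. Endothelial-like cells were not fitted, nor fibroblast-like with 50 cells per library or macrophage-like cells in batch 1. Unless a reason is given, the cause was not tested.

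With DESeq2, counts were 120 for dura and 142 for blood mature B cells by age, 52 for pre-B-like cells of dura against marrow, 7 for marrow pre-B-like cells by age, 8 for monocyte-like, 13 for neutrophil-like and 27 for fibroblast-like cells. Without a filter on low counts they were 325, 82, 73 and 62 for the 4 B cell fits in the same order, 396 for T-like, 66 for macrophage-like, 57 for monocyte-like, 99 for neutrophil-like and 200 for fibroblast-like cells, as genes with near 0 counts were then tested too. Without TMM dura against blood mature B cells had 3743. At a UMI minimum of 1000 dura mature B cells had 125, macrophage-like cells 16 and neutrophil-like cells 2. Macrophage-like cells had 19 with at least 50 cells per library, and fibroblast-like cells 35 with doublets kept. Without the ABC-like and B1-like clusters dura mature B cells had 3.

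Without the batch term counts were 36 for dura and 19 for blood mature B cells, 134 for T-like, 13 for macrophage-like, 2 for monocyte-like, 2 for neutrophil-like and 8 for fibroblast-like cells. In batch 1 alone, with fewer libraries, they were 2 for dura and 0 for blood mature B cells, 272 for dura against blood, 38 for T-like, 0 for monocyte-like, 0 for neutrophil-like and 7 for fibroblast-like cells, and in batch 2 alone 47, 116, 145 for T-like, 14 for macrophage-like, 9 for monocyte-like, 14 for neutrophil-like and 22 for fibroblast-like cells. The main fits and share tests did not treat same-numbered libraries as pairs (tests of V segments and ABC-like cells by number did), since the share of pairs with like residuals differed between tissues (6 of 7 in aged dura and blood, 5 of 6 in young and aged blood, 0 of 7 in young and aged dura, with 6, 4 and 2 best with their own number, a hint from the data). A replicate block in place of batch gave 121 for dura mature B (24 of 26 named calls kept), 43 for blood mature B (0 of 6 kept), 23 for dura against marrow, 26 for marrow pre-B-like, 45 for macrophage-like, 56 for monocyte-like, 16 for neutrophil-like and 32 for fibroblast-like cells. In shares it ended the calls of plasma-like cells in dura (adjusted exact p = 0.107) and young pro-B-like cells against blood (0.0625). By age it left 3 B stages and 0 blood classes called. Blood NK-like cells had adjusted exact p = 0.172, and ABC-like (5.88 points) and B1-like cells (14.3) 0.125. With 6 pairs a class cannot pass alone, so this is undecided.

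With 1 library left out, counts ran from 33 to 153 for dura and 7 to 137 for blood mature B cells, 0 to 1 for the interaction, 1205 to 1840 for dura against blood, 4 to 64 for dura against marrow, 6 to 39 for marrow pre-B-like, 174 to 273 for T-like, 13 to 35 for macrophage-like, 0 to 10 for monocyte-like, 2 to 24 for neutrophil-like and 6 to 28 for fibroblast-like cells. Of the named genes called, those kept in every omission were 14 of 26 in dura and 0 of 6 in blood mature B cells, 32 of 33 for dura against blood, 2 of 7 for dura against marrow, 3 of 12 for marrow pre-B-like, 13 of 17 for T-like, 1 of 14 for macrophage-like, 0 of 3 for neutrophil-like and 5 of 10 for fibroblast-like cells. The libraries whose omission lost most were young dura library 5 (11 genes in mature B cells), aged blood library 6 (6, as did others), young marrow library 3 (8), and young dura library 3 (10 in macrophage-like cells).

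Called leukocyte classes numbered 4 to 7 in dura, 0 to 3 in blood and 2 to 5 non-overlapping ones in marrow with 1 library left out (5 without aged marrow library 1, 4 without library 2). B stages called by age numbered 4 to 6, and those non-overlapping in marrow 1 to 3 (2 without aged marrow library 1 or 3 or young marrow library 2, 3 without young marrow library 3). In permutations within batches 3 age calls of B stages were kept, and the difference of ABC-like cells of blood, 5.15 points, had an adjusted exact p of 0.0514. Developing stages of the dura differed by age by 17.7 points in batch 1 and -11.1 in batch 2, and by -2.29 to 3.15 with 1 library left out. Reversed were the B lineage share in dura in batch 1 (1.14), the T-like share in dura in batch 2 (2.17), the B lineage share in blood at a UMI minimum of 1000 (0.762), in batch 2 (4.44) and in omissions (-7.00 to 0.839), the neutrophil-like share in marrow (-1.07 to 4.40) and the developing share in blood in batch 2 (-0.617) and in omissions (-1.18 to 1.70). For dura minus marrow, omissions gave -5.87 to 0.581 for young and -3.11 to 12.3 for aged developing stages (-3.60 with cluster 5 as mature), -5.03 to 0.889 for aged cycling pre-B-like cells, with 7.40 at a UMI minimum of 1000, and -5.95 to 1.65 for aged pre-B-like cells.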

Other observations

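The tests of marrow and blood carry-over, of V segment use and of ABC-like cells within mature B cells were chosen only after the results were seen. On average ABC-like cells of aged mice drew on fewer heavy chain V segments than mature-like cells, with aged blood library 1 as an exception (9.409 segments). Among 10 such cells, drawn repeatedly, 5.31 ± 2.38 segments were seen in aged blood (SD, n = 7 libraries) and 4.70 ± 2.13 in aged dura (n = 5), against 9.12 ± 0.0412 and 9.33 ± 0.353 among 10 mature-like cells (n = 7 each). The share of ABC-like cells within mature B cells was higher in dura than in blood in 7 of 7 aged numbers, at 20.8% ± 15.7 against 5.46% ± 5.27 (exact sign-flip p = 0.0156, exact unpaired p = 0.0251).

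The leading V segment of ABC-like cells was the same in dura and blood of 4 of 5 numbers compared. It was Ighv1-82 in number 2 (76.9% of dura and 80.2% of blood cells), Ighv1-53 in numbers 3 (70.4% and 78.7%) and 7 (24.2% and 55.3%) and Ighv1-12 in number 4 (68.7% and 60.7%). Blood cells left in the dura are argued against, since 7 of 7 numbers had a higher ABC-like share of mature B cells in dura than in blood. For number 2 this argument is weak, as its gap rests largely on the B1-like cells of its blood library. V segment transcripts from free RNA are argued against, since the leading segment reached at most 7.1429% of mature-like cells of the same library. The explanation that ABC-like cells of one mouse share expanded clones across tissues fits, since V segment use overlapped by 67.5% between same-numbered and 14.0% between other libraries (exact one-sided p = 0.0083333). It stays a hypothesis, because it is not stated that equal numbers mark the same mouse, a V segment is not a clonotype, the same segment led in several numbers (dura 3 overlapped blood 7 by 63.16%, and dura 7 did by 35.57%), and within batches the exact p was 0.0833, the smallest possible.

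Cells at pre-B-like stages in the dura could have come with another tissue. B cells carried over with blood are argued against, since the lowest young dura library had 47.59% developing cells and the highest young blood library 6.01%. Marrow cells carried into the dura cannot be told apart, because the marrow next to the dura is that of the skull, which was not sampled. Against tibial marrow, immature-like per pre-B-like cell was 5.0946 times higher in dura (young, batch 1, medians, exact p = 0.1), 3.38 times over all young dura libraries, 1.51 times in aged batch 1 and 3.00 times over all aged. Within each age dura and marrow libraries did not overlap, but with cluster 5 as mature they did, other than in young batch 1. Progenitors per pre-B-like cell were 2.2352 times those of marrow in young batch 1 (exact p = 0.2), 0.774 times over all young dura libraries (exact p = 0.9) and 0.621 times in aged mice (exact p = 0.8 in batch 1), with overlapping ranges. HSPC-like cells alone were at 0.475 to 0.866 times in these comparisons. Development within the dura stays open and was not tested.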
